A study of Mus musculus with 14 samples.

How the data were processed

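Poly(A) RNA of tibialis anterior muscle from C57Bl/6 mice was measured by RNA sequencing in 14 libraries, prepared with an Illumina TruSeq RNA kit per the labels. The libraries were grouped by treatment and day as labelled: 3 control and 4 follistatin libraries at day 3, 2 and 2 at day 7, and 1 and 2 at day 14. Days 7 and 14 were combined as the chronic set of 3 control and 4 follistatin libraries, as the series' design does. The labels do not state how follistatin was given, what the controls received, the strand setting of the libraries, or whether replicates were separate animals. The authors' comparisons are named MCS against FST, so MCS stands for the control arm.

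The authors aligned the reads with TopHat to the mouse genome build mm10 and computed FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) with Cuffdiff, per the labels. No versions, counting mode or annotation are stated. The deposited files hold FPKM per gene and library, and 2 deposited tables hold the authors' Cuffdiff test for day 3 and for the chronic set. These tables hold, as computed by the authors with Cuffdiff from the aligned reads, log2 fold changes, test scores (Cuffdiff's test statistic), unadjusted p-values and q-values (p-values adjusted for the false discovery rate). Each library file lists 24386 genes. Of these, 27 whose symbols had been turned into dates were left out, and 24359 were used. Genes that the authors' table marks as having too many reads to be estimated (HIDATA, 4 at day 3 and 31 in the chronic set) were left out of the tests, because their FPKM can be listed as 0 where no estimate was made.

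Read counts were not used here, so the absolute depth is unknown. Relative depth was taken from the steps between low values: FPKM under 0.5 of the same gene in 2 libraries differ by a ratio of whole read numbers (up to 6) times the ratio of depths. With a tolerance of 0.02 on the log2 scale, 79.2% to 83.8% of the low values of day 3 libraries and 43.5% to 59.4% of those of chronic libraries met such a ratio against control day 3 replicate 1. The precision of low values is therefore known only relative to that library.

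Each set was fitted alone with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2(FPKM + 1), over genes with a mean of at least 1 FPKM in the set, as follistatin minus control. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The added 1 makes log2 changes of genes with low FPKM smaller than the ratio of their means. The difference of the effects of both sets was tested as an interaction over all 14 libraries. Shared calls were compared with chance by Fisher's exact test over genes tested in both sets. The Fst level was also tested by an exact two-sided permutation test over the 35 splits of the 7 libraries of a set.

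A set of 43 gene lists covering signalling, protein synthesis and breakdown, fibre type, metabolism, stress, matrix, immune genes and markers of other cell types was fixed before the data were examined. The lists of T and NK cells and of B and plasma cells had fewer than 5 tested members, and the other 41 were tested with limma's camera. It asks whether a list moved relative to all other genes, with a preset correlation of 0.01 between genes, and again with the correlation estimated per list. Members were counted by the gene test, adjusted over all genes and adjusted over the list alone. The list of the ankyrin repeat and SOCS box family was written knowing that the study followed Asb2. Some genes stand on more than 1 list, among them Casq2.

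The rule for named genes was also fixed before the data were examined. It takes Fst, Mstn, Igf1, Asb2, Fbxo32 and Trim63. In each set it adds the 8 called genes with the largest rise and the 8 with the largest fall whose follistatin and control libraries do not overlap, without predicted genes, clones and pseudogenes. It also takes the 2 members with the smallest p, in the direction of the list, of each called list, and the 5 genes with the largest called difference between the sets. Genes outside this rule are marked as chosen after their values were seen. One gene that the rule takes is not reported here. Positions are from GENCODE M21 on mm10 (GRCm38), which was also searched for exon bases that a named gene shares with another gene.

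Alternatives, whose effect the closing section gives, were a pseudocount of 0.1, no filter on low values or a mean of at least 5 FPKM, rescaling by the median ratio, quantile normalization, robust eBayes, a replicate block (by day and replicate number, which leaves out the follistatin library that has no control of its number), a limit of 1.5-fold, all 14 libraries in 1 fit, day as a covariate, the day 7 libraries alone, the estimated correlation, and leaving out each library in turn. Leaving out the 1287 small RNA genes of the files, and keeping the genes marked HIDATA, were added after the data were seen.

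The pipeline was tested on simulated data with 200 changed genes, all drawn from those with a mean of at least 10 FPKM. Recovery of genes between 1 and 10 FPKM was therefore not measured. At day 3, 63.2%, 89.2% and 100% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 10 false calls among 175. In the chronic design these shares were 38.4%, 76.6% and 93.7%, with 3 false calls among 139. For the difference between sets they were 35.7%, 70.1% and 89.6%, with 12 false calls among 146. A list shifted by 0.4 on the log2 scale was called in both designs, with 0 other lists called by camera, and also with the estimated correlation (adjusted p = 0.000255 and 0.00247). The simulated genes varied independently of each other. Real lists did not, with an estimated correlation of 0.788 for ribosomal proteins in the chronic set. The simulation therefore does not test false calls among such lists, or camera with their estimated correlation. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.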

Results

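RNA of the tibialis anterior, a muscle at the front of the lower leg, was sequenced from mice whose muscles had been treated with follistatin or were controls. Follistatin is a secreted protein that binds activins and myostatin, members of the TGF-beta family that limit muscle growth. Day 3 held 3 control and 4 follistatin libraries. The chronic set held 3 control libraries (2 of day 7 and 1 of day 14) and 4 follistatin libraries (2 of each day). The labels do not say whether replicates were separate animals, so all p-values measure only the spread between these libraries. Values are FPKM as the authors scaled them, and group values are given as mean ± SD over libraries.

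The FPKM of a library summed to between 364513 and 532859. The number of reads is not in the files. Relative to control day 3 replicate 1, depth was 0.683 to 1.27 in the day 3 libraries and 3.09 to 4.63 in the chronic libraries. Control day 7 replicate 1 listed 16158 genes above 0, against 19383 to 20283 in the other chronic libraries and 15766 to 17161 in those of day 3. This conflicts with its relative depth of 4.63, the highest of all, so the depth of this library is uncertain. Replicates of a group correlated across genes at Pearson's r of 0.930 to 0.952 on the log2 scale.

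The first question was how much follistatin mRNA the treated muscles held. Fst, the gene of follistatin (chromosome 13, 114452290 to 114458951, minus strand), lay at 1.18 ± 0.212 FPKM in the controls of day 3 (n = 3) and at 57.6 ± 8.16 FPKM in the follistatin libraries (n = 4), 48.7-fold higher. At day 7 the follistatin libraries held 387 ± 28.7 FPKM (n = 2) and at day 14 1368 ± 75.3 FPKM (n = 2), while the 3 controls of these days lay between 0.808 and 1.17 FPKM. The log2 fold change was 4.74 (SE 0.12, adjusted p = 6.5e-07) at day 3 and 8.51 (SE 0.51, adjusted p = 0.000841) in the chronic set, 874-fold by the means. With the block by day and replicate number, which also takes out follistatin day 14 replicate 2, the chronic rise did not pass (adjusted p = 0.0597 by limma). All 4 follistatin libraries lay above all controls in each set, and the exact permutation p was 0.0286 in each, the smallest that 35 splits can give. Follistatin level and day of treatment rise together from day 3 to day 14 and cannot be separated by these samples. Since the labels do not state how follistatin was given, mRNA of the muscle's own Fst gene cannot be told from any follistatin mRNA supplied by the treatment.

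**Figure D1:**
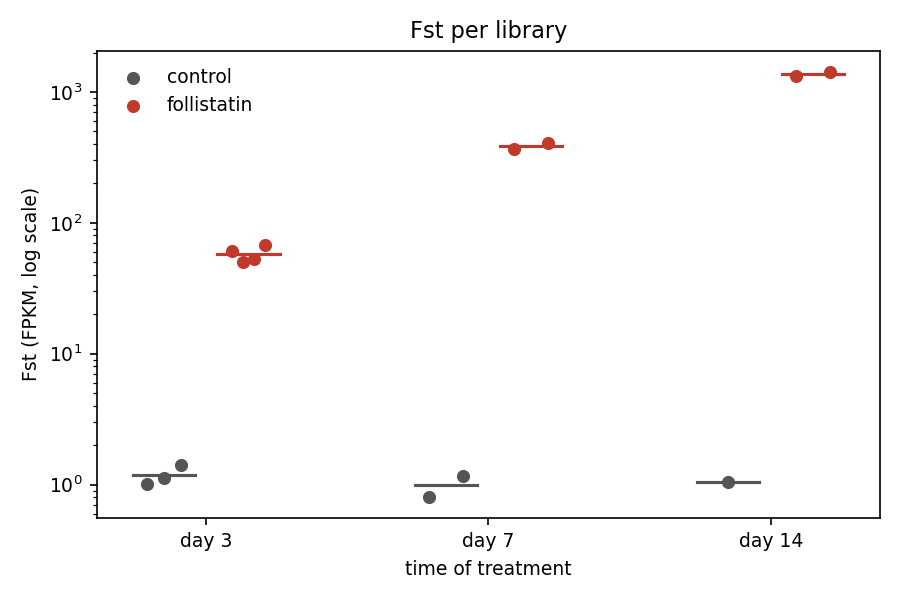
Fst per library in FPKM on a log axis (points) with the mean of each group (bars), by day of treatment; day 14 has 1 control library. Controls lie between 0.808 and 1.42 FPKM on all days, and follistatin libraries average 57.6, 387 and 1368 FPKM at days 3, 7 and 14.

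At day 3, the earliest time after treatment, muscles treated with follistatin held less mRNA of Asb2 and Chac1 and more mRNA of Actc1 and Mybph than controls. Asb2, a subunit of a ubiquitin ligase (chromosome 12, 103321142 to 103356001, minus strand), fell from 118 ± 6.85 to 35.4 ± 3.63 FPKM (log2 fold change -1.72, SE 0.09, adjusted p = 0.00012). Chac1, an enzyme that degrades glutathione, had the largest fall, from 38.5 ± 18 to 3.27 ± 1.97 FPKM (-3.24, SE 0.41, adjusted p = 0.011). Actc1, the cardiac form of alpha-actin, rose from 240.8 ± 43.8 to 822 ± 163 FPKM (1.76, SE 0.17, adjusted p = 0.00338). Mybph, a myosin-binding protein, rose from 21.1 ± 3.93 to 70.8 ± 20.8 FPKM (1.67, SE 0.23, adjusted p = 0.0133).

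Among the other genes with the largest rise were Tceal7 (14.1 ± 3.6 to 49.6 ± 21.9 FPKM), the growth factor gene Fgf6 (2.04 ± 0.236 to 7.51 ± 2.26 FPKM) and Ppp1r3c, which targets a phosphatase to glycogen (40.1 ± 4.85 to 112 ± 27.5 FPKM). The adenosine receptor gene Adora1 was listed at 3.14 ± 0.335 and 9.92 ± 2.58 FPKM, but it shares 1162 exon bases with Mybph on the opposite strand. Among the genes with the largest fall were the growth arrest gene Gadd45b (22.96 ± 0.615 to 7.60 ± 0.545 FPKM), Mpp3 (9.13 ± 0.922 to 3.51 ± 0.272 FPKM) and Mss51 (6.84 ± 2.43 to 1.07 ± 0.453 FPKM). Others were Igfn1 (7.69 ± 3.11 to 1.55 ± 0.267 FPKM), Prima1 (-1.42, or -2.17 with a pseudocount of 0.1) and Tmem100 (-1.35 on the log2 scale). The microRNA gene Mir6935 was called as well and was listed at 0 in all 3 controls. Its values in the 4 follistatin libraries equal 1 or 2 smallest steps, and it lies within an exon of Actg1. For every gene named so far in this comparison, all follistatin libraries lay on 1 side of all controls, because the rule takes only such genes.

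Of the genes named in advance for muscle mass, Trim63 (MuRF1), a ubiquitin ligase of muscle wasting, fell from 133 ± 6.13 to 93.3 ± 5.35 FPKM at day 3 (-0.50, adjusted p = 0.013). Fbxo32 (atrogin-1) did not pass the test, at 43.5 ± 8.9 against 22.8 ± 6.19 FPKM (-0.92, adjusted p = 0.0961). Neither did the myostatin gene Mstn, at 17.1 ± 0.876 against 28.2 ± 6.51 FPKM (0.67, adjusted p = 0.0811), or the growth factor gene Igf1 (0.24, adjusted p = 0.549; 0.05 and 0.37 without control replicates 2 and 3). Without small RNA genes Mstn and Fbxo32 were called (0.0365 and 0.0382), and Mstn also with robust eBayes (0.0404) and without follistatin replicate 1 (0.045).

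In all, limma called 168 of the 11268 genes tested at day 3, 104 higher and 64 lower with follistatin, and 1711 genes had an unadjusted p under 0.05. The groups did not overlap in 15.1% of the genes tested, against 5.71% by chance. The count was 39, 51 and 80 without control replicates 1, 2 and 3, 105 without follistatin replicate 1, and 266 without the small RNA genes. Asb2, Mir6935, Actc1, Mss51, Gadd45b, Mpp3, Pdia6, Hspa5, Sypl2 and Ulk1 were called with any 1 library left out. Of the 25 genes named as called besides Fst, 14 were not called without control replicate 1 (adjusted p from 0.0534 to 0.164), 13 without control 2 (0.0519 to 0.171) and 6 without control 3 (0.0529 to 0.131). Without follistatin replicates 1, 2, 3 and 4 it was 5, 2, 6 and 1 of them (0.0501 to 0.0987). All 14 libraries in 1 fit ended the calls of Actc1, Tceal7, Pdia6, Hspa5, Odc1, Azin1, Xirp1 and Sqstm1 (0.0501 to 0.218), and a block by day and replicate number ended 19 calls (0.071 to 0.217). That block also takes out the follistatin library that has no control of its number, here and in the chronic set. Tceal7 was also not called with rescaling, quantile normalization, no filter on low values or robust eBayes (0.0518 to 0.121). Xirp1 was not called with quantile normalization or no filter (0.0554 and 0.0676), nor Azin1 with no filter (0.0508).

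The lists of chaperones of the endoplasmic reticulum (ER), ribosomal proteins, ribosome biogenesis and polyamine genes lay higher at day 3 by camera. Of 24 chaperones and unfolded protein response genes of the ER, 3 rose, 0 fell and 21 did not pass, and 12 rose when adjusted over the list alone. Camera gave an adjusted p = 2.33e-07, and an adjusted p = 0.331 with an estimated correlation. Hspa5, the main ER chaperone (BiP), rose from 83.9 ± 3.53 to 145 ± 13.4 FPKM, and Pdia6 from 21.2 ± 0.288 to 35.1 ± 1.99 FPKM. The other was Manf (0.75), named after its value was seen. Of 77 ribosomal protein genes 0 passed by limma (13 higher and 2 lower at an unadjusted p under 0.05, 0 adjusted over the list alone), with 59 above 0 and camera's adjusted p = 0.00341 (adjusted p = 0.737 with an estimated correlation). Rpl15 stood at a log2 fold change of 0.31 and Rpl5 at 0.28, and both share exon bases with a gene on the opposite strand. Of 35 ribosome biogenesis genes 0 passed by limma (8 higher and 1 lower unadjusted, 0 adjusted over the list alone), with a median of 0.09, 28 above 0 and camera's adjusted p = 0.00971 (adjusted p = 0.591 with an estimated correlation). Nop16 stood at 0.39 and Nolc1 at 0.28, and without follistatin replicate 4 the median was 0.14. Of 13 polyamine genes 3 rose and 10 did not pass, the count adjusted over the list alone being 3 as well (camera's adjusted p = 0.0392, and adjusted p = 0.591 with an estimated correlation). They were Odc1, the first enzyme of polyamine synthesis (31.6 ± 1.89 to 44.6 ± 3.05 FPKM), its regulator Azin1 (0.74), and Mat2a (0.50), which was named after its value was seen.

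The lists of embryonic contractile, calcium handling, mechanical stress and synapse genes lay higher as well. Of 11 embryonic and neonatal contractile genes 3 rose, also when adjusted over the list alone. All 11 were above 0 and the median log2 fold change was 0.74 (camera's adjusted p = 8.35e-05, and adjusted p = 0.591 with an estimated correlation). Without follistatin replicate 2 the median was 0.46. The 3 were Actc1, Mybph and Casq2 (0.94, named after its value was seen). Casq2 is the cardiac and slow-fibre calsequestrin, and no developmental myosin of the list passed. Of 21 genes of calcium handling and the triad, where the muscle membrane meets its calcium store, 3 rose and 18 did not pass, and 7 rose and 2 fell when adjusted over the list alone (camera's adjusted p = 0.00864, and adjusted p = 0.339 with an estimated correlation). Sypl2 (mitsugumin 29) rose from 146 ± 6.8 to 235 ± 17 FPKM, Bin1 from 236 ± 12.8 to 332 ± 8.52 FPKM, and the other was again Casq2. Of 18 mechanical stress and muscle damage genes Xirp1 alone rose (0.66), against 3 higher and 1 lower when adjusted over the list alone (camera's adjusted p = 0.0132, and adjusted p = 0.591 with an estimated correlation). Hspb1 stood at 0.70 with an adjusted p = 0.0693. Of 24 synapse, denervation and regeneration genes 0 passed by limma (3 higher unadjusted, 0 adjusted over the list alone) with 19 above 0 (camera's adjusted p = 0.0202, and adjusted p = 0.716 with an estimated correlation). Sln stood at 1.52 and Rapsn at 0.30.

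Autophagy, respiration, clock and antigen presentation genes lay lower at day 3. Of 27 autophagy genes 2 fell and 25 did not pass, and 3 fell when adjusted over the list alone (camera's adjusted p = 0.000421, and adjusted p = 0.331 with an estimated correlation). Ulk1, the kinase that starts autophagy, fell from 21.7 ± 1.53 to 12.9 ± 0.303 FPKM, and the autophagy receptor gene Sqstm1 from 279 ± 10.6 to 208 ± 7.79 FPKM. Of 76 oxidative phosphorylation genes 0 passed by limma (4 lower unadjusted, 0 adjusted over the list alone), with a median of -0.09 and 14 above 0 (camera's adjusted p = 0.000421, and adjusted p = 0.716 with an estimated correlation). Uqcr11 stood at -0.36 and Uqcrq at -0.31. The median was -0.01 without control replicate 2 (adjusted p = 0.597) and -0.05 without follistatin replicate 1. Of 16 clock genes 0 passed by limma (3 lower unadjusted, 0 adjusted over the list alone; camera's adjusted p = 0.0165, and adjusted p = 0.331 with an estimated correlation). Bhlhe40 stood at -0.59 and Per1 at -0.27, or Per1 at -0.16 without control replicate 1. Of 19 antigen presentation genes 0 passed by limma (4 lower unadjusted, 0 adjusted over the list alone; camera's adjusted p = 0.0392, and adjusted p = 0.716 with an estimated correlation). Psmb9 stood at -0.53 and Tapbp at -0.23.

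Markers of endothelial cells, smooth muscle and fibroblasts lay lower at day 3, beside the groups above. Of 20 endothelial markers none was above 0, with a median log2 fold change of -0.22. Of the 20, 0 passed by limma (7 lower unadjusted) and 3 fell when adjusted over the list alone (camera's adjusted p = 9.08e-06, and adjusted p = 0.331 with an estimated correlation). Without control replicate 2 the median was -0.14. Cdh5 stood at 39.9 ± 1.52 against 31.7 ± 2.16 FPKM and Pecam1 at 34.7 ± 0.0837 against 28.2 ± 2.2 FPKM. Of 14 smooth muscle and pericyte markers 0 passed by limma (5 lower unadjusted, 0 adjusted over the list alone; median -0.21, camera's adjusted p = 0.00554, and adjusted p = 0.591 with an estimated correlation). Kcnj8 stood at -0.42 and Higd1b at -0.77. Of 20 markers of fibroblasts and fibro-adipogenic progenitors 0 passed by limma (5 lower unadjusted) and 3 fell when adjusted over the list alone (median -0.19, camera's adjusted p = 0.00864, and adjusted p = 0.716 with an estimated correlation). Gsn stood at -0.39 and Dpt at -0.35. The median was -0.10 without control replicate 1 (adjusted p = 0.19) and -0.11 without follistatin replicate 3 or 4.

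In all, camera called 15 of 41 lists at day 3, 8 higher and 7 lower, and 0 with the estimated correlation (5 at an unadjusted p under 0.05). Other splits of the 7 libraries called up to 18 lists. The other 26 lists had adjusted p between 0.0776 and 0.954. For signalling and protein turnover these were activin, myostatin and TGF-beta components, TGF-beta response, BMP, ubiquitin ligases and atrophy (median -0.06), the ankyrin repeat and SOCS box family, IGF, Akt and mTOR, translation factors, proteasome, and amino acid and ATF4 genes. For fibre type, metabolism and growth they were slow fibre, fast fibre, glycolysis, the tricarboxylic acid cycle, fatty acid oxidation, myogenic regulators, immediate early genes and proliferation. The others were collagens, interferon response, complement, and markers of macrophages, neutrophils, Schwann cells, adipocytes, tendon and red blood cells. Some calls of lists ended without single libraries. Without control replicate 1 they were 4 (ribosomal proteins, adjusted p = 0.111, synapse, 0.0783, clock, 0.0524, and fibroblasts, 0.19), without control 2 they were 3 (polyamine, 0.112, respiration, 0.597, and synapse, 0.163), and without control 3 antigen presentation alone (0.225). Without follistatin 1 antigen presentation was not called (0.0592), and without follistatin 2 ribosomal proteins (0.0772) and synapse (0.104). Without follistatin 3 ribosomal proteins (0.156) and mechanical stress (0.0994) were not called, and without follistatin 4 polyamine (0.114) and antigen presentation (0.132). The call of respiration also ended with quantile normalization (0.0678, median -0.04), and that of antigen presentation with a mean of at least 5 FPKM (0.0742). The block ended those of polyamine (0.155) and antigen presentation (0.183).

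In the chronic set, which asks for the state after 7 to 14 days, Actc1, Mybph and Tceal7 stood far higher with follistatin than in controls, and myoglobin and Asb2 lower. Actc1 rose from 337 ± 252 to 4039 ± 2326 FPKM (log2 fold change 3.80, SE 0.73, adjusted p = 0.0315), with 5939 and 6161 FPKM at day 7 and 2122 and 1933 FPKM at day 14. Mybph rose from 20.7 ± 10.1 to 219 ± 19.8 FPKM (3.45, SE 0.30, adjusted p = 0.00261), and Tceal7, which shares 223 exon bases with Bex1, from 19.7 ± 1.55 to 350 ± 155 FPKM (3.96, SE 0.36, adjusted p = 0.00286). Mb, the oxygen-binding protein myoglobin, fell from 3465 ± 719 to 886 ± 371 FPKM (-2.04, SE 0.31, adjusted p = 0.0148). Asb2 fell from 184 ± 16.9 to 40.5 ± 10 FPKM (-2.18, SE 0.19, adjusted p = 0.00266).

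Serpinb1a, a protease inhibitor, rose from 2.36 ± 0.843 to 18.6 ± 10.9 FPKM, and Adora1 was listed at 2.43 ± 1.02 and 34.5 ± 4.84 FPKM, again with exon bases shared with Mybph. Among the genes with the largest fall were Nos1, the neuronal nitric oxide synthase (18.6 ± 3.32 to 5.03 ± 1.93 FPKM), Klhl38 (13.5 ± 2.33 to 3.32 ± 0.945 FPKM), Tmem100 (9.68 ± 3.03 to 1.66 ± 0.666 FPKM), Igfn1 (8.50 ± 5.36 to 0.741 ± 0.354 FPKM) and Mss51 (-2.07, adjusted p = 0.0405). Of the microRNA genes called, Mir6340, which lies within an exon of Rab22a, and Mir8102 were listed at 0 in all controls, with follistatin values of 1 or 2 smallest steps. Mirlet7d was listed at 0 in all follistatin libraries, and its values in the 3 controls come to about 6 smallest steps in all. Fbxo32 fell from 49.1 ± 3.99 to 19.96 ± 4.62 FPKM (-1.28, SE 0.18, adjusted p = 0.0117). Trim63 (-0.40, adjusted p = 0.0737), Mstn (18.9 ± 5.5 against 36.8 ± 14.2 FPKM, adjusted p = 0.15) and Igf1 (-0.15, adjusted p = 0.688) did not pass. With single libraries left out, Igf1 ranged from -0.35 (without control day 14 replicate 1) to -0.003 (without control day 7 replicate 2). Trim63 was called with all 14 libraries in 1 fit (0.00839), with quantile normalization (0.0434) and without follistatin day 14 replicate 2 (0.0445), and Mstn without follistatin day 7 replicate 1 (0.0402).

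**Figure D2:**
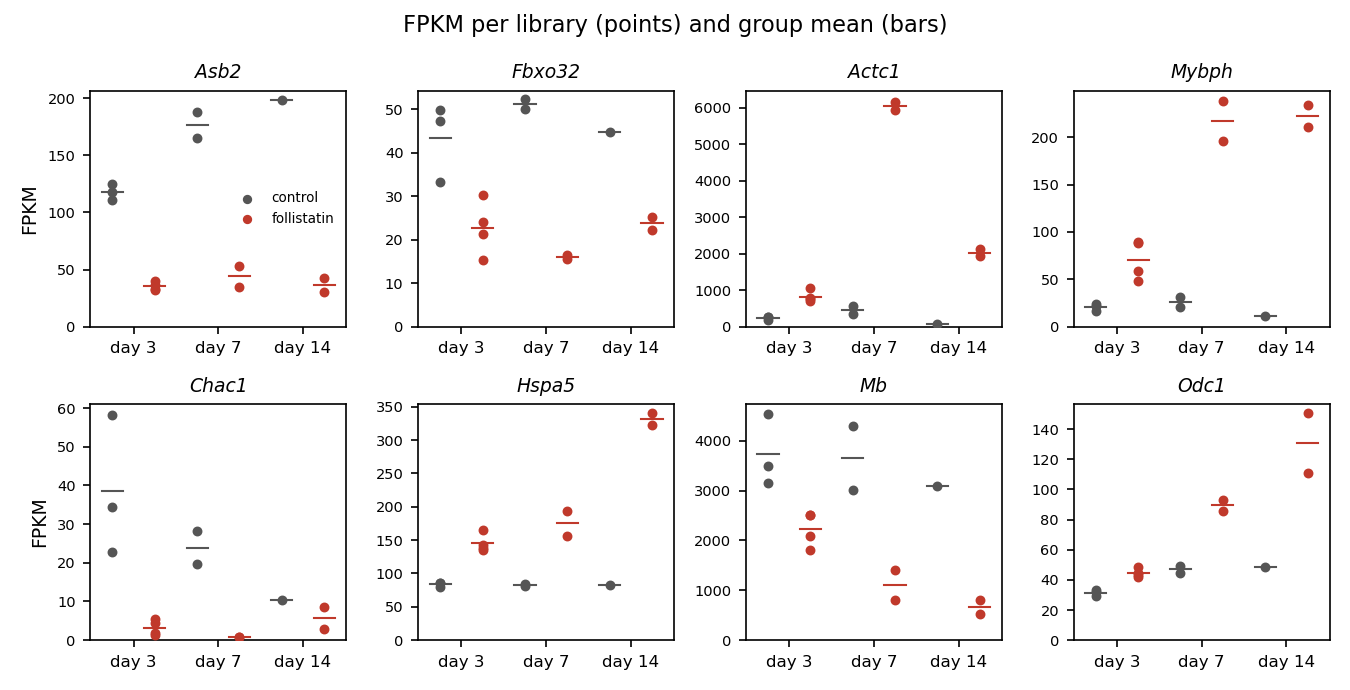
FPKM per library of 8 named genes (points) with group means (bars), control in grey and follistatin in red, at days 3, 7 and 14; axes differ between genes and day 14 has 1 control library. Asb2 stays at 35.4 ± 3.63 FPKM at day 3 and 40.5 ± 10 FPKM in the chronic set with follistatin, while Hspa5 averages 145, 175 and 332 FPKM at days 3, 7 and 14.

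Limma called 608 of the 11047 genes tested in the chronic set, 247 higher and 361 lower, and 3124 genes had an unadjusted p under 0.05. The groups did not overlap in 30.4% of the genes tested, against 5.71% by chance. The balance of directions turned with the scaling. The median log2 fold change of all genes was -0.09 with the authors' scaling, while rescaling by the median ratio gave 388 higher and 250 lower genes and quantile normalization 414 and 326. The count was 43, 145 and 62 without control day 7 replicate 1, control day 7 replicate 2 and control day 14 replicate 1. It was 405 without follistatin day 7 replicate 2 and 251 without follistatin day 14 replicate 1. Further counts were 30 with the day 7 libraries alone, 284 with no filter on low values, and 963 without small RNA genes. All 14 libraries in 1 fit gave 2071 (613 higher, 1458 lower), and the block by day and replicate number gave 0.

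Asb2, Tceal7, Mybph, Adora1, Mir6340, Mir8102, Mirlet7d, Tmem100, Klhl38 and Asb15 were called in the chronic set with any 1 library left out. Of these, Mir6340, Mir8102 and Mirlet7d rest on about 4, 5 and 6 smallest steps in all. Of the 31 genes named as called by the rule besides Fst, 21 were not called without control day 7 replicate 1 (adjusted p from 0.0726 to 0.194), 14 without control day 7 replicate 2 (0.0504 to 0.132), and 20 without control day 14 replicate 1 (0.0531 to 0.162). The number was 3 and 6 without follistatin day 7 replicates 1 and 2, and 10 and 2 without follistatin day 14 replicates 1 and 2 (0.0509 to 0.0921). With the day 7 libraries alone 22 calls ended (0.0572 to 0.362), and with the block, which rests on 3 pairs of libraries and also takes out follistatin day 14 replicate 2, all 31 (0.0597 to 0.152). No filter on low values ended those of Actc1, Serpinb1a, Mss51, Aldh18a1, Azin1, Cryab, Ube2c, Pik3c3 and Tek (0.054 to 0.0832). Robust eBayes ended those of Actc1, Serpinb1a and Mss51 (0.053 to 0.0662), quantile normalization that of Mss51 (0.053), and day as a covariate those of Azin1 and Ube2c (0.0656 and 0.0623).

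The lists of ER chaperones, ribosomal proteins, ribosome biogenesis and proteasome subunits lay higher in the chronic set by camera. Of 24 ER chaperone genes 6 rose, 0 fell and 18 did not pass, and 14 rose when adjusted over the list alone (median 0.54, camera's adjusted p = 1.02e-09, and adjusted p = 0.574 with an estimated correlation). Pdia6 rose from 21.2 ± 1.18 to 61.1 ± 18.3 FPKM and Sec61b, part of the channel into the ER, from 26.0 ± 1.33 to 52.2 ± 10.6 FPKM. All 76 ribosomal protein genes were above 0, with a median of 0.32. By limma 0 passed (21 higher unadjusted, 0 adjusted over the list alone; camera's adjusted p = 5.42e-14, and adjusted p = 0.574 with an estimated correlation). Rpl10 stood at 0.54 and Rpsa at 0.74. The rise was not seen in every library. The list mean of follistatin day 14 replicate 1 (7.57) lay within those of the controls (7.55 to 7.71), against 7.91 to 8.26 in the other follistatin libraries. Ribosomal protein genes have many near-identical pseudogenes, whose reads cannot be told from theirs in FPKM. Of 35 ribosome biogenesis genes 0 passed by limma (6 higher and 1 lower unadjusted, 0 adjusted over the list alone; camera's adjusted p = 0.0051, and adjusted p = 0.574 with an estimated correlation). Nhp2 stood at 0.61 and Bop1 at 0.40. Of 31 proteasome subunits 28 were above 0, and 0 passed by limma (5 higher unadjusted, 0 adjusted over the list alone; median 0.18, camera's adjusted p = 8.08e-05, and adjusted p = 0.574 with an estimated correlation). Psmd6 stood at 0.36 and Psmd8 at 0.57, and without follistatin day 14 replicate 2 the median was 0.08.

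Of 28 amino acid synthesis, tRNA charging and ATF4 genes 1 rose in the chronic set, also when adjusted over the list alone: Aldh18a1, an enzyme of proline synthesis, from 2.58 ± 0.604 to 6.46 ± 1.86 FPKM. The list had camera's adjusted p = 0.000374, and adjusted p = 0.574 with an estimated correlation. Of the 28, 22 were above 0. The list means of the day 7 follistatin libraries (3.74 and 3.81) lay within those of the controls (3.71 to 3.84), and only those of day 14 (4.04 and 4.22) lay above. Chac1, another member, went the other way. It averaged 23.9 FPKM in controls and 0.741 FPKM with follistatin at day 7, and 10.3 and 5.79 FPKM at day 14. Psat1 stood at 0.80 with an adjusted p = 0.0851, at 1.39 with a pseudocount of 0.1 and at 0.42 with the day 7 libraries alone. Of 13 polyamine genes 2 rose, also when adjusted over the list alone (camera's adjusted p = 0.0296, and adjusted p = 0.574 with an estimated correlation). They were Odc1 (47.5 ± 2.48 to 110 ± 29 FPKM) and Azin1 (16.2 ± 1.07 to 38.2 ± 11.5 FPKM). Of 13 proliferation genes Ube2c alone rose, and 4 rose when adjusted over the list alone (camera's adjusted p = 0.0229, and adjusted p = 0.574 with an estimated correlation). Ube2c stood at 0.665 ± 0.211 against 2.09 ± 0.726 FPKM and shares 592 exon bases with the abundant fast troponin gene Tnnc2. Rrm2 stood at 0.62 with an adjusted p = 0.0544, or at 1.11 with a pseudocount of 0.1.

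Of 20 calcium handling genes 4 rose and 1 fell in the chronic set, and 6 rose and 1 fell when adjusted over the list alone (median 0.10, camera's adjusted p = 0.00508, and adjusted p = 0.574 with an estimated correlation). Sypl2 rose from 205 ± 19.5 to 406 ± 39 FPKM and Casq2 from 25.7 ± 4.37 to 65.9 ± 14.5 FPKM. The others, named after their values were seen, were Bin1 (0.81), Dysf (0.47) and the calcium release channel gene Ryr1 (-0.71). Of 18 mechanical stress genes 3 rose and 1 fell, and 5 rose and 3 fell when adjusted over the list alone (camera's adjusted p = 0.00869, and adjusted p = 0.574 with an estimated correlation). The small heat shock protein genes Hspb1 (83.7 ± 4.52 to 245 ± 67.4 FPKM) and Cryab (492 ± 7.31 to 1157 ± 380 FPKM; 252 exon bases shared with Hspb2) rose, as did Tnfrsf12a (1.13), while Ankrd23 fell (-0.86), both named after their values were seen. Of 8 embryonic and neonatal contractile genes the 3 of day 3, Actc1, Mybph and Casq2, rose, also when adjusted over the list alone. Of the 8, 4 were above 0, and the median was 0.11 and the mean 0.98 (camera's adjusted p = 0.0238, and adjusted p = 0.574 with an estimated correlation). The median was 0.21 without control day 7 replicate 2 and 0.18 without follistatin day 14 replicate 1. It was 1.31 with a mean of at least 5 FPKM, 0.19 with rescaling, 0.22 with quantile normalization and -0.07 with no filter or with the genes marked HIDATA kept.

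The lists of ubiquitin ligases, the ankyrin repeat family, autophagy and the tricarboxylic acid cycle lay lower. Of 29 ubiquitin ligase and atrophy genes 4 fell and 25 did not pass, against 9 lower and 1 higher when adjusted over the list alone (median -0.24, camera's adjusted p = 0.0458, and adjusted p = 0.574 with an estimated correlation). They were Fbxo32, the transcription factor gene Foxo4 (60.8 ± 5.24 to 27.6 ± 5.71 FPKM), and Fbxo31 (-0.63) and Klf15 (-0.70), named after their values were seen. Of 16 genes of the ankyrin repeat and SOCS box family, to which Asb2 belongs, 6 fell, and 7 fell and 1 rose when adjusted over the list alone (median -0.48, camera's adjusted p = 0.0285, and adjusted p = 0.574 with an estimated correlation). Since the list was written knowing that the study followed Asb2, this is not independent evidence of its direction. Without follistatin day 14 replicate 2 the median was -0.30. Asb15 fell from 15.7 ± 1.28 to 4.70 ± 1.27 FPKM. The others, named after their values were seen, were Asb11 (-1.02), Asb14 (-0.78), Asb4 (-0.58) and Asb13 (-0.51). Of 27 autophagy genes 3 fell, and 6 when adjusted over the list alone (median -0.29, camera's adjusted p = 0.00869, and adjusted p = 0.574 with an estimated correlation). The 3 were Ulk1 (21.8 ± 2.21 to 11.5 ± 1.34 FPKM), Pik3c3 (7.91 ± 0.527 to 5.28 ± 0.248 FPKM) and Map1lc3b (-0.60, named after its value was seen). Of 28 tricarboxylic acid cycle genes and mitochondrial regulators 0 passed by limma (12 lower unadjusted, 0 adjusted over the list alone; median -0.30, camera's adjusted p = 0.0458, and adjusted p = 0.631 with an estimated correlation). Ogdh stood at -0.50.

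Markers of endothelial cells, smooth muscle and Schwann cells lay lower beside these groups in the chronic set, and those of macrophages higher. Of 19 endothelial markers 1 fell, and 13 fell when adjusted over the list alone (median -0.55, camera's adjusted p = 0.00017, and adjusted p = 0.574 with an estimated correlation). The 1 was Tek (9.21 ± 1.54 to 4.69 ± 1.13 FPKM), while Pecam1 stood at 33.4 ± 4.57 against 22.5 ± 2.55 FPKM. Of 14 smooth muscle and pericyte markers 0 passed by limma (9 lower and 1 higher unadjusted), against 7 lower and 1 higher when adjusted over the list alone (median -0.67, camera's adjusted p = 0.0458, and adjusted p = 0.631 with an estimated correlation). Tagln stood at -0.87 and Mylk at -0.65, or at -0.51 and -0.43 with the day 7 libraries alone. Of 6 Schwann cell markers 0 passed by limma (4 lower unadjusted), and 4 fell when adjusted over the list alone (median -0.77, camera's adjusted p = 0.0458, and adjusted p = 0.628 with an estimated correlation). With no filter the median was -0.27. Mbp stood at -1.29 and Pmp22 at -0.81, or at -0.60 and -0.39 with the day 7 libraries alone. Macrophage and monocyte markers lay higher, 20 of 21 above 0 with a median of 0.65. By limma 0 passed (0 unadjusted, 0 adjusted over the list alone; camera's adjusted p = 0.000185, and adjusted p = 0.574 with an estimated correlation). The median was 0.42 without control day 14 replicate 1 and 0.30 without follistatin day 14 replicate 2. Mrc1 stood at 3.58 ± 1.8 against 6.12 ± 1.86 FPKM and Spp1 at 10.4 ± 6.84 against 19.5 ± 8.66 FPKM, with log2 fold changes of 0.67 and 0.92. These were 0.42 for Mrc1 without control day 14 replicate 1 and 0.25 with the day 7 libraries alone, and 0.57 for Spp1 without control day 7 replicate 2. Of 19 antigen presentation genes, 1 of which is also a macrophage marker, 15 were above 0 and 0 passed by limma (1 higher unadjusted, 0 adjusted over the list alone; median 0.31, camera's adjusted p = 0.00869, and adjusted p = 0.697 with an estimated correlation). The median was 0.12 and 0.48 without control day 7 replicates 1 and 2, and 0.53 and -0.01 without follistatin day 14 replicates 1 and 2. Psme2 stood at 0.49 and H2-DMa at 1.00, or at 0.52 without follistatin day 14 replicate 2, which held 12.1 FPKM of it against 2.43 to 2.56 in the other follistatin libraries.

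In all, camera called 19 of 41 lists in the chronic set, 12 higher and 7 lower, and 0 with the estimated correlation (1 at an unadjusted p under 0.05). Another split of the 7 libraries also called 19. The other 22 lists had adjusted p between 0.053 and 0.917. For signalling and protein synthesis these were activin, myostatin and TGF-beta components, TGF-beta response, BMP, IGF, Akt and mTOR, and translation factors. For fibre type and metabolism they were slow fibre, fast fibre (5 tested members), glycolysis, oxidative phosphorylation (its test pointed up and its median was -0.003), and fatty acid oxidation. The others were myogenic regulators, synapse, immediate early genes, clock, collagens, interferon response, complement, and markers of neutrophils, fibroblasts, adipocytes, tendon and red blood cells. Some calls of lists ended without single libraries here as well. Without control day 7 replicate 1 they were ubiquitin ligases (adjusted p = 0.0525), polyamine (0.0567), the tricarboxylic acid cycle (0.112), antigen presentation (0.0606) and smooth muscle (0.0747). Without control day 14 replicate 1 Schwann cells were not called (0.111). Without follistatin day 7 replicate 1 this held for ubiquitin ligases (0.11), the ankyrin repeat family (0.0609) and contractile genes (0.083), and without replicate 2 for ubiquitin ligases (0.0598), the tricarboxylic acid cycle (0.061) and Schwann cells (0.061). Without follistatin day 14 replicate 1 it held for the tricarboxylic acid cycle (0.0788), smooth muscle (0.0545) and Schwann cells (0.0901). Without its replicate 2 it held for ubiquitin ligases (0.0845), the tricarboxylic acid cycle (0.0845), proliferation (0.0501), antigen presentation (0.125, median -0.01), smooth muscle (0.0665) and Schwann cells (0.094).

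Other settings moved medians or ended calls of chronic lists too. Rescaling gave medians of 0.29 for proteasome subunits, 0.20 for calcium handling and -0.14 for ubiquitin ligases, and the block 0.08 for proteasome subunits, -0.30 for the ankyrin repeat family and 0.29 for macrophage markers. Day as a covariate ended those of ubiquitin ligases (0.0567), the tricarboxylic acid cycle (0.055) and Schwann cells (0.0567), and rescaling that of the tricarboxylic acid cycle (0.086). Quantile normalization ended those of polyamine (0.0715) and calcium handling (0.0813), and no filter those of polyamine (0.0917) and contractile genes (0.149, median -0.07). A mean of at least 5 FPKM ended those of ubiquitin ligases (0.0908), the tricarboxylic acid cycle (0.0908) and smooth muscle (0.145). The block, without follistatin day 14 replicate 2, ended those of ubiquitin ligases (0.123), the ankyrin repeat family (0.0654), polyamine (0.072), the tricarboxylic acid cycle (0.0654), antigen presentation (0.388, median -0.01) and Schwann cells (0.155).

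**Figure D3:**
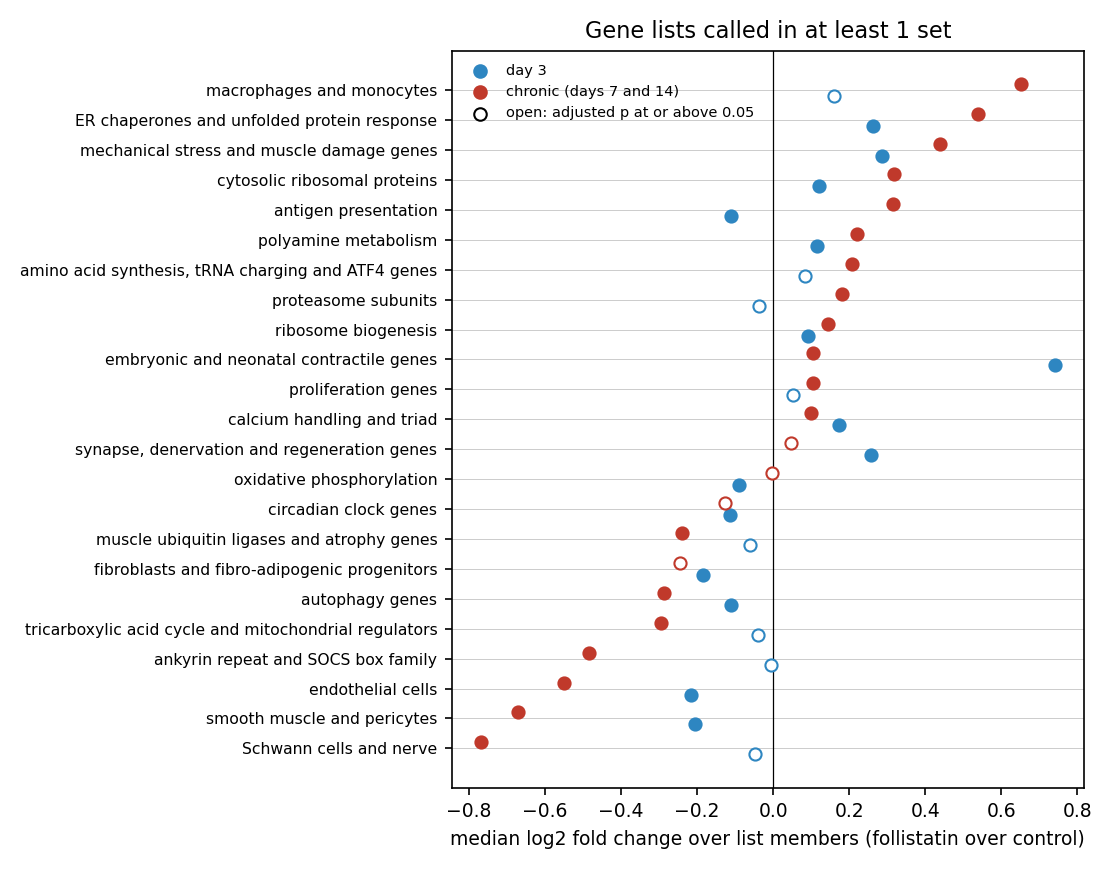
Median log2 fold change over the members of each list that camera called in at least 1 set, at day 3 (blue) and in the chronic set (red); open circles are lists with an adjusted p of 0.05 or more. ER chaperones have medians of 0.26 and 0.54 and endothelial markers of -0.22 (-0.14 without control replicate 2) and -0.55; none of these calls holds with an estimated correlation.

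The effects of both times were then compared. The Asb2 fall and the rises of Actc1, Mybph, Tceal7 and Adora1 were among 98 genes called in the same direction in both sets, 47 higher and 51 lower, and 0 genes were called by limma in opposite directions. Chance would give 2.25 and 2.16 such genes among the 10643 genes tested in both (Fisher's exact p = 1.62e-80, and genes are not independent). A limit of 1.5-fold left 69 shared calls, and the block by day and replicate number left 0. Of the 168 genes called at day 3, 163 had the same sign in the chronic set and 106 a larger change there. Of the 589 chronic calls tested in both, 541 had the same sign at day 3. Across these genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.377 and Spearman's rho 0.456. Camera called 10 lists in the same direction in both sets, all lost with an estimated correlation (adjusted p from 0.331 to 0.737 at day 3 and from 0.574 to 0.631 in the chronic set), and chance was not computed for shared lists. It called antigen presentation lower at day 3 and higher in the chronic set (adjusted p = 0.716 and adjusted p = 0.697 with an estimated correlation). Without follistatin day 14 replicate 2 its chronic median was -0.01 (adjusted p = 0.125). The difference between sets was not tested for lists.

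**Figure D4:**
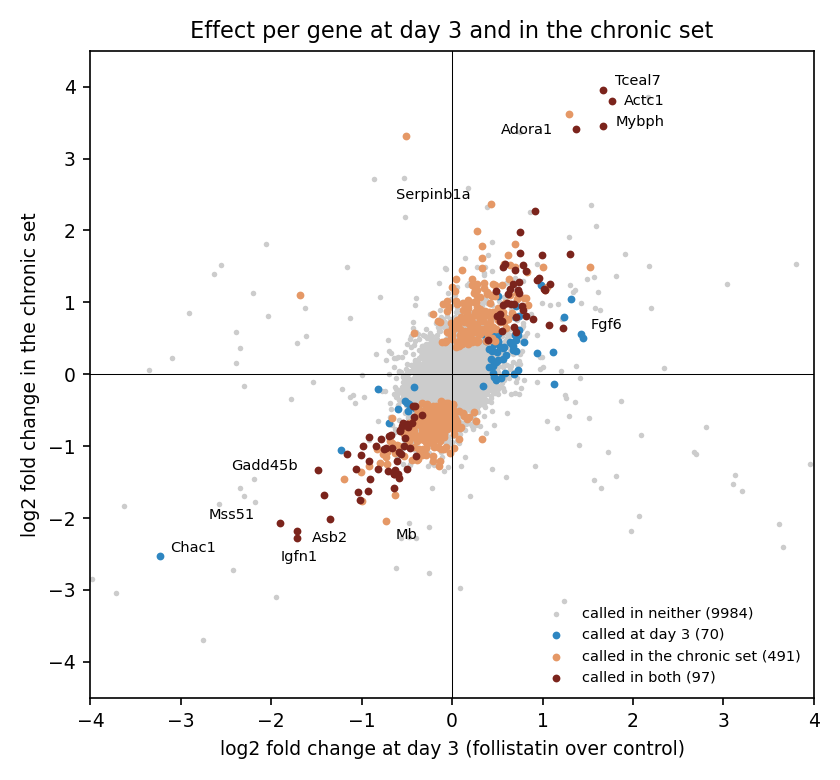
Log2 fold change of each gene (follistatin over control) at day 3 against that in the chronic set, coloured by where the gene was called: 70 at day 3 alone, 491 in the chronic set alone, 97 in both and 9984 in neither. Fst is left out and 6 genes lie outside the axes; the genes called in both sets lie in the lower left and upper right of the plot.

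The difference of the effects, chronic minus day 3, was called for 10 of 11306 genes, 7 higher and 3 lower, with 1678 at an unadjusted p under 0.05. Fst had the largest, 3.77 (SE 0.56, adjusted p = 0.0322), followed by the microRNA gene Mir8102 (2.88, or 6.01 with a pseudocount of 0.1), whose values are 1 or 2 smallest steps. Mir8102 was listed at 0 in every library of day 3, where depth was lower, so its difference is its chronic effect alone. Adora1 differed by 2.04 (SE 0.30, adjusted p = 0.0322). Gamt, the last enzyme of creatine synthesis, had a log2 fold change of 0.33 (adjusted p = 0.291) at day 3 and 1.79 (adjusted p = 0.00391) in the chronic set, a difference of 1.46 (SE 0.23, adjusted p = 0.0322). Tceal5 rose by 0.92 and 2.27, a difference of 1.35 (SE 0.21, adjusted p = 0.0322). The count was 4, 2 and 3 without control replicates 1, 2 and 3 of day 3, and 4, 4 and 2 without follistatin replicates 1, 2 and 3 of day 3. It was 4 without control day 7 replicate 1, 6 without control day 14 replicate 1, 32 and 22 without follistatin replicates 1 and 2 of day 7, and 5 without follistatin day 14 replicate 1. Leaving out control day 3 replicate 1, 2 or 3, control day 7 replicate 1, or follistatin day 3 replicate 1 or 3 ended the calls of Fst, Adora1, Gamt and Tceal5 (adjusted p from 0.0565 to 0.149), as did no filter on low values (0.0632) and the block (0.368 to 0.448). Robust eBayes ended that of Fst (0.0866). Some of them also ended without control day 14 replicate 1 (Fst, 0.0879; Gamt and Tceal5, 0.132), control day 7 replicate 2 (Fst, 0.052), follistatin day 3 replicate 2 (Fst and Gamt, 0.0622) and follistatin day 14 replicate 1 (Adora1, 0.0541; Tceal5, 0.0642).

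The authors' deposited tables of Cuffdiff tests mark 602 of 9625 tested genes as significant at day 3, 295 higher and 307 lower, and 2259 of 12664 in the chronic set, 841 higher and 1418 lower. Of the 168 genes limma called at day 3, 160 are marked in the authors' deposited table, and of the 608 in the chronic set 563 are. Among genes tested here, the direction of change was the same for all 602 genes marked in the authors' deposited table of day 3 and for 2001 of 2002 in that of the chronic set. Both tests rest on the same libraries, so neither the shared marks nor the directions are independent evidence. With at least 1.5-fold, the marks of the authors' deposited tables come to 251 at day 3 and 1777 in the chronic set.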

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

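The tests of splits, of larger effects, of shared reads and of cell types, and the depth test for genes of at least 20 FPKM, were chosen only after the result was seen; the depth test for genes under 20 FPKM was set before its value was seen.

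The number of genes called was compared with all 35 splits of the 7 libraries of a set into 3 and 4. At day 3, 1 of the 35 splits, the real one, called as many as 168 genes, and the highest other called 3. In the chronic set, 1 of 35 called as many as 608, and the highest other called 5. A share of 1 of 35 is the smallest that these splits can give. The other splits also mix treated with control libraries, so a real effect adds to their spread and lowers their counts. The real split thus called the most genes in both sets, which does not exclude chance. For the lists chance is not excluded: 5 of 35 splits called at least the 15 lists of day 3, and the highest called 18 (control replicates 1 and 2 with follistatin replicate 4 against the others), and 2 of 35 called at least the 19 lists of the chronic set, the highest other being 19. For the difference between the sets, 7 of 100 splits called at least 10 genes, the highest calling 1479, but these splits carry the effect common to both sets into the difference, so they do not measure chance. With the common effect removed first, 1 of 100 splits, the real one, called as many as 10 and the highest other 9. This margin of 1 gene is small beside the range of 2 to 32 calls with single libraries left out. Chance is therefore not excluded for this count.

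Adora1 was called higher with follistatin in both sets and with a larger effect in the chronic set, but it shares 1162 exon bases with Mybph on the opposite strand. The ratio of Adora1 to Mybph FPKM was 0.138 to 0.170 in controls and 0.132 to 0.151 with follistatin at day 3, and 0.111 to 0.129 and 0.128 to 0.198 in the chronic set. The log2 ratio differed by 0.384 in the chronic set (exact permutation p = 0.0857) and by -0.09 at day 3 (exact permutation p = 0.429), so the ranges overlap in both. Reads of Mybph counted for Adora1 may therefore account for its change. A true rise of both genes together stays open, since FPKM cannot tell the strands apart.

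The chronic set has more calls than day 3 and libraries 4.82 times as deep by the median. Among the 2508 genes of at least 20 FPKM, 97 and 212 genes were called. There the median difference of same-group library pairs was 2.206 times that of day 3. The residual SD was 1.73 times that of day 3 (1.41 to 1.87 with single libraries left out), which argues against depth as the cause there. The argument rests on the 2 follistatin pairs (0.266 and 0.279), and the residual SD also holds the mix of days. It does not hold for controls: their only chronic pair, of day 7, differed by 0.0984, below all day 3 pairs (0.109 to 0.158). The median absolute effect of these genes was 1.96 times that of day 3 (1.76 to 2.20), in line with larger effects; the spread it includes is larger too, and longer treatment, more follistatin and the mix of days are confounded. Among the 8135 other genes, with 71 and 377 calls, the residual SD ratio was 1.14 (0.993 to 1.21). Their median absolute effect was 1.81 times that of day 3 (1.59 to 2.03 with single libraries left out), and it includes the spread as well. Depth cannot be told apart from larger effects for these genes, because the range of the SD ratio includes 1.

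In the chronic set markers of endothelial cells, smooth muscle and Schwann cells lay lower and macrophage markers higher. A larger share of muscle fibre RNA would lower all of these alike, yet the macrophage minus endothelial list means differed by 1.103 between follistatin and control (log2; exact permutation p = 0.114), and by 0.706 without follistatin day 14 replicate 2, where 3 against 3 libraries are too few for the test to pass. This share cannot be told apart from changes in the cells themselves, because the difference did not pass over the 7 libraries. Without follistatin day 14 replicate 2 the macrophage list was still called by camera at the preset correlation (adjusted p = 0.00614). The list mean of control day 7 replicate 2 (2.58) then lay above those of all remaining follistatin libraries (2.20 to 2.36). Whether the call rests on that 1 library is therefore not settled. With all libraries the list had an adjusted p = 0.574 by camera with an estimated correlation. Of its 21 members 0 passed by limma (0 unadjusted). A change in cell numbers in the treated muscle stays open and was not tested.

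The effect differed between the sets by the interaction test for 10 genes: Fst by 3.77, Mir8102 by 2.88, Adora1 by 2.04, Gamt by 1.46, Tceal5 by 1.35, and, named after their values were seen, Tubb4b by 1.27 (0.05 at day 3, 1.32 in the chronic set), Tuba4a by 1.13 (0.03 and 1.16), Nudt4 by -0.84 (0.10 and -0.74), Serpine2 by -0.79 (0.19 and -0.60) and Zfp180 by -0.70 (-0.05 and -0.76). Their adjusted p ranged from 0.00144 to 0.0437 by limma. For Mir8102, listed at 0 in every day 3 library, the difference is the chronic effect alone.

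In the follistatin libraries of day 3, Per1 lay at 12.5 FPKM in replicate 3 and at 11.5 to 11.6 FPKM in the others, a gap of 0.8867 of the whole range; by Dixon's rule for 4 values it was the only 1 of 63 tests to pass, and chance passes about 1 in 20.

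Among the chronic genes that the authors' table leaves untested for too many reads, 4 lay higher in all follistatin than in all control libraries: Casq1 by 1.40-fold, Eno3 by 1.24-fold, Mybpc2 by 1.48-fold and Tpm2 by 1.44-fold of the means, each with an exact permutation p = 0.0286, which became 0.107 when adjusted over the 15 genes of both sets marked this way, 3 of them at day 3, with values above 0 in every library.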

How the results depend on the processing

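Leaving out small RNA genes and keeping the genes marked as having too many reads were chosen only after the data were seen; all other alternatives were planned. No named gene's test or list's camera test changed direction under any alternative, over 139 results; which library or setting ended a call stands with each comparison. Of the named genes not called in the chronic set, 15 were called with all 14 libraries in 1 fit (adjusted p from 0.00446 to 0.0326), 10 without small RNA genes, 8 with a mean of at least 5 FPKM, 7 with robust eBayes, 6 with quantile normalization, 6 without follistatin day 7 replicate 1, 5 with rescaling, 3 with a pseudocount of 0.1, and 1 each without follistatin day 14 replicate 1 and 2. At day 3, besides Mstn and Fbxo32, Hspb1 was called with a mean of at least 5 FPKM, robust eBayes, without small RNA genes and without follistatin replicate 4 (0.0261 to 0.0467), and Nop16 with a mean of at least 5 FPKM (0.0456). With single libraries left out, the Fst log2 fold change ranged from 4.66 to 4.82 at day 3 and from 8.19 to 8.84 in the chronic set, the calls from 39 to 165 and from 43 to 907, the lists from 11 to 19 and from 14 to 24, and the differences between sets from 2 to 32. With the estimated correlation 0 lists were called by camera in each set (5 and 1 at an unadjusted p under 0.05). A limit of 1.5-fold left 100 calls at day 3 and 251 of the authors' marks at day 3. Without small RNA genes there were 266 and 963 calls, and with the marked genes kept 24 differences between sets. No filter on low values gave 284 chronic calls and 2 differences between sets, all 14 libraries in 1 fit gave 2071 chronic calls (613 higher, 1458 lower), and the day 7 libraries alone, 2 against 2, gave 30; the causes were not tested, beyond fewer libraries in the last. A replicate block, by day and number, leaves 3 pairs per set and also takes out the follistatin library without a partner, so its losses are not those of the block alone. It gave 13 calls at day 3, 0 in the chronic set by limma (2612 at an unadjusted p under 0.05), 0 shared calls, 3 differences between sets, and a chronic Fst effect of 8.19 (adjusted p = 0.0597, against a range of 1.5e-07 to 0.0597 over its alternatives). At day 3 controls correlated with the follistatin library of their own number at -0.05, -0.06 and -0.03 over genes, and none of the 3 best with it. The numbers thus gave no sign of pairing at day 3. This cannot exclude it, because paired muscles need not share a spread that such a correlation shows, and the labels leave pairing open. At day 7 both controls went best with their own number, at 0.0143 each, which with 2 libraries per group is 1 value and does not decide whether they are paired. Without reads per gene the depth limits could be given only relative to 1 library.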

Other observations

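The comparison of follistatin libraries of day 14 with those of day 7 and its test of the ER chaperone list were chosen only after the result was seen, and the genes named here, except Gamt and Fst, were chosen after their values were seen.

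Both enzymes of creatine synthesis stood higher in the chronic follistatin libraries. Gatm rose from 2.75 ± 0.434 to 10.5 ± 4.91 FPKM (log2 fold change 1.51, adjusted p = 0.043 by limma) and Gamt from 9.73 ± 1.90 to 36.1 ± 6.48 FPKM (1.79, adjusted p = 0.00391). Cidea, a lipid droplet protein, rose from 1.10 ± 0.362 to 4.93 ± 1.09 FPKM (1.49, adjusted p = 0.00876). The tubulin genes Tubb4b (103 ± 11.4 to 259 ± 19.6 FPKM) and Tuba4a (292 ± 56.1 to 645 ± 25.8 FPKM) rose as well. For each of these genes all 4 follistatin libraries lay above all 3 controls.

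Members of the activin and TGF-beta pathway were called although their lists were not. Of 24 pathway components 1 rose and 4 fell in the chronic set and 0 rose and 3 fell at day 3, and of the response genes 0 rose and 3 of 17 fell in the chronic set and 0 rose and 1 of 18 fell at day 3, by limma (at an unadjusted p under 0.05, 3 and 2 components and 2 and 2 response genes lay higher in the chronic set and at day 3). The inhibin gene Inha rose by 0.79 in the chronic set (adjusted p = 0.0499). In the chronic set Skil, a feedback inhibitor of TGF-beta signalling, fell by 1.20 on the log2 scale, the activin receptor genes Acvr1b by 1.03 and Acvr2b by 0.58, and the response gene Pmepa1 by 0.95. At day 3 Skil fell by 0.92, Acvr1b by 0.75 and Ltbp3 by 0.52. Skil stands on both lists and is counted in each, and it was the 1 response gene that fell at day 3. The counts of the lists are therefore not separate. The list of pathway components had camera's adjusted p of 0.609 at day 3 and 0.142 in the chronic set.

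Of the genes marked as having too many reads in the chronic set, Myh2, a fast myosin, lay 0.303-fold, the giant protein gene Neb 0.733-fold and the glycogen phosphorylase gene Pygm 0.824-fold as high with follistatin as in controls, with no overlap of the groups (exact permutation p = 0.0571, 0.114 and 0.0571, which became 0.143, 0.19 and 0.143 when adjusted over the 15 marked genes of both sets with values above 0). Of the 31 genes marked this way, 18 were listed at 0 in every follistatin library and 8 at 0 in every control, which does not measure absence.

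A candidate explanation for the spread of ER chaperone genes within the chronic follistatin libraries is that they follow the Fst level, which was 387 FPKM at day 7 and 1368 FPKM at day 14. The list's median difference, day 14 minus day 7, was 0.55 on the log2 scale, with 23 of 24 members above 0, camera's adjusted p = 8.27e-16, and adjusted p = 0.497 with an estimated correlation. The list means of 4.85 and 4.96 at day 14 lay above those of 4.20 and 4.45 at day 7. From day 3 to day 7 they did not rise with Fst. With Fst at 57.6 FPKM, the follistatin libraries of day 3 had list means of 4.25 to 4.37, within those of day 7. The controls had 3.94 to 4.05 at day 3 and 3.97 at day 7. Single members can differ, as Hspa5 averaged 145 and 175 FPKM with follistatin at days 3 and 7. With 2 libraries per day, the day itself or another difference between the pairs of libraries explains the rise from day 7 to day 14 as well, and 17 other lists were called between these days. Among them were macrophage markers with a median of 0.70 (adjusted p = 0.568 with an estimated correlation) and collagens with -0.55 (adjusted p = 0.564 with an estimated correlation). Markers of tendon (-0.78), adipocytes (-0.64), endothelial cells (-0.45) and fibroblasts (-0.38) lay lower at day 14 (each adjusted p = 0.497 with an estimated correlation), as did those of smooth muscle (-0.51; adjusted p = 0.564 with an estimated correlation). In this comparison limma called 15 of 10940 genes, with 501 at an unadjusted p under 0.05.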
